A study of Danio rerio with 4 samples.

How the data were processed

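The series holds RNA-seq libraries of distal regenerating caudal fin tissue from zebrafish 96 hours after amputation, 2 from *longfin* heterozygotes and 2 from wildtype clutchmates, each from the pooled tissue of 4 fins. Genotype and replicate number were taken from the sample labels. Per the labels' protocols, tissue was homogenised in TRIzol and libraries were made with a Kapa stranded mRNA kit. Per the submitters' processing notes, the authors used TopHat2 and HTSeq with the GRCz11 (danRer11) build. The tools' versions, the annotation release, the strand setting and the overlap mode of the counting are not given in the sources used here. The strand setting decides whether overlapping antisense genes can be told apart, so values of such genes are uncertain.

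The deposited files hold raw read counts per Ensembl gene ID, made by the authors and not normalized. Each lists 31901 gene IDs, a row without a name that equals the sum of the gene rows, and 5 HTSeq classes of unassigned reads. These last 6 rows stayed out of library sizes and tests. Of each library's reads in gene rows and HTSeq classes, 28.7 to 41.9% were not uniquely aligned, 7.78 to 9.31% lay in no gene and 1.08 to 1.38% were ambiguous. Wildtype replicate 1 had the highest share that was not unique (41.9%), followed by longfin heterozygous replicate 2 (36.6%). Reads in genes numbered 19428186 to 23157979. The 3 most abundant genes (*zgc:158463*, *col1a1a* and ENSDARG00000080337) took 8.2 to 11.7% of them. TMM factors lay between 0.945 and 1.04. Counts of the 2 libraries of a genotype did not agree within sampling noise (chi-square per degree of freedom 29.8 in wildtype and 20.6 in longfin), so neither was treated as a copy of the other.

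Gene symbols came from a table of Ensembl IDs, which names 29178 of the 31901 IDs and gives many zebrafish genes the capital symbol of their human orthologue. Where several IDs carry one symbol, the ID is printed. Of 856 entries in 30 gene lists, 800 were matched, 213 of them by the human symbol, so that a list can hold both zebrafish copies, and 56 were not matched. RefSeq positions of the GRCz12tu assembly were used only to find which genes neighbour *kcnh2a*, and no coordinates are given because the authors' build differs.

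Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16, with filterByExpr by genotype (minimum count 10, minimum total 15), TMM scaling, the version 4 quasi-likelihood fit (glmQLFit with legacy fitting off and robust on) and glmQLFTest for genotype, two-sided, without a replicate term. It was fitted to all 4 libraries. P-values were adjusted by Benjamini-Hochberg over the 18366 genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.134. CPM values are scaled by TMM and given as mean ± SD over 2 libraries, fold changes are log2 of longfin heterozygous over wildtype, and standard errors are the fold change divided by the square root of the F statistic. Both KCNH2 genes fell below the filter, so their counts were summed per genotype and compared by an exact conditional test given the scaled library sizes, with a 95% interval. That interval covers counting error only.

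The 30 gene lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. Lists, tests and alternatives added later are said to be so where they appear. The lists covered the kcnh channel family, other K+ channels and gap junctions linked to fin size, calcineurin and NFAT, voltage-gated Ca2+ channels, the Wnt, Fgf, retinoic acid, Hedgehog and Bmp, and Notch and activin pathways, blastema mesenchyme, actinotrichia and fibrillar matrix, matrix metalloproteinases, fin ray joint, osteoblasts, basal and superficial epidermis, ionocytes and mucous cells, endothelium, red blood cells, macrophages and neutrophils, lymphocytes, pigment cells, nerve and glia, skeletal muscle, S phase, G2/M phase, immediate early and heat shock genes, hypoxia and glycolysis, interferon response and mitochondrially encoded proteins. Lists with at least 5 tested members were compared with other genes by camera (limma 3.58.1) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over 28 lists. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone.

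Named genes were the kcnh family, the 12 largest rises and 12 largest falls among genes past the threshold with genotypes that did not overlap, a mean CPM of at least 1 and a symbol that is not a clone or locus name, per list up to 4 members past the threshold or otherwise the 2 of highest CPM, and the 4 tested genes nearest to *kcnh2a* with any that passed within 1 Mb. Genes named outside the rule are said to be so or are the members of a small count.

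Alternatives were DESeq2's size factors, upper quartile scaling and library size only in place of TMM, no low count filter, a mean count of at least 50, DESeq2 1.42.0, limma voom, edgeR's older quasi-likelihood fit, a replicate block, a minimum fold change of 1.5 (glmTreat), windows of 500 kb and 2 Mb, and leaving out each library in turn. With 1 library left in a genotype, its spread is assumed to equal that of the other. A test of whether changed genes gather on the chromosome of *kcnh2a* was void, because 48 of the 74 changed genes (64.9%) had a RefSeq position, below the 80% required. No correction for GC content or length was run, since the tables used here give no GC values. With 2 libraries per genotype no test for outlying libraries was run.

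The scripts were tested on simulated data for 18366 genes in 2 against 2 libraries with the real means, library sizes and spread. EdgeR recovered 68% of genes changed 2-fold and 89% of those changed 4-fold, all in the right direction. Of its 174 calls, 17 (9.77%) were false, above the nominal 5%. In a simulated comparison of 28 lists, a list of 30 genes raised 1.5-fold had an adjusted p of 6.39e-42 with camera's preset correlation, 0.113 with an estimated correlation and 0.0503 with fry. None of the unchanged simulated lists was called by any of these tests. Genes were drawn independently of each other, so the simulation cannot show false list calls that arise from correlation between genes. Figures were drawn with matplotlib.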

Results

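RNA was sequenced from regenerating caudal fins of adult zebrafish (*Danio rerio*) 96 hours after amputation. The fish were *longfin* heterozygotes, which carry 1 copy of a dominant allele that gives overgrown fins, or wildtype clutchmates. All carried an sp7:eGFP transgene, which labels osteoblasts, and the tissue taken was the GFP-negative tip of the regenerate that lies distal to the labelled cells. Each library held the pooled tips of 4 fins, and there were 2 libraries per genotype. Reads assigned to genes numbered 21801279 and 19428186 in longfin heterozygous replicates 1 and 2, and 19602564 and 23157979 in wildtype replicates 1 and 2. Between 23473 and 23966 genes had at least 1 read. No source says whether the pools of 1 genotype came from separate clutches or days, so p-values measure only the spread between these samples.

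The study's title places ectopic expression of the potassium channel gene *kcnh2a* at the *longfin* locus, so its level was read first. The gene-name table gives the symbol KCNH2 to 2 counted genes and does not say which of them is *kcnh2a*, so both are reported. The first, ENSDARG00000029881, had 7 and 21 reads in the longfin libraries against 0 and 1 in the wildtype libraries. As CPM, the count scaled to library size, this was 0.315 and 1.08 against 0 and 0.0417. Summed per genotype, the longfin to wildtype ratio was 28.5, with a 95% exact conditional interval of 4.72 to 1170. As log2 the ratio was 4.83, and it was 5.52 without longfin heterozygous replicate 1, 3.74 without longfin heterozygous replicate 2 and 4.01 without wildtype replicate 1, while without wildtype replicate 2 the wildtype count was 0 and no ratio is given. The two-sided exact conditional test gave p = 4.57e-08, which covers counting error only and compares these libraries. The second gene, ENSDARG00000106473, had 1 and 3 reads in the longfin libraries and 4 and 1 in the wildtype libraries, a ratio of 0.815 with an interval of 0.162 to 3.79, so no difference was detectable at this depth, and with a library left out its log2 ratio lay between -1.39 and 1.2. Both fell below the count filter of the gene-wide test. Without the filter, ENSDARG00000029881 had a log2 fold change of 4.53 and an adjusted p of 0.229 in edgeR's quasi-likelihood test.

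**Figure D1:**
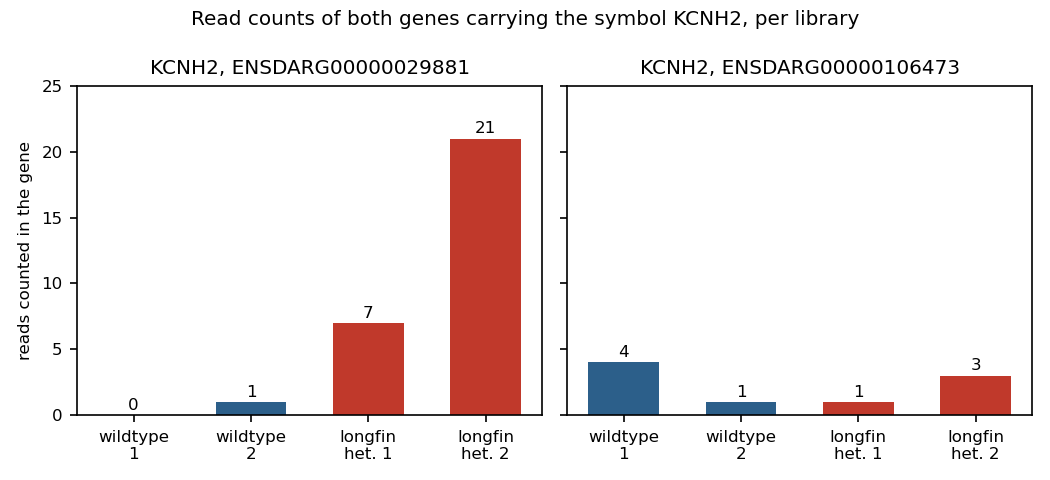
Reads counted in each library for both genes that carry the symbol KCNH2. Bars are single libraries, wildtype in blue and longfin heterozygous in red. ENSDARG00000029881 had 7 and 21 reads in the longfin libraries and 0 and 1 in the wildtype libraries.

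Among other channels of the ether-a-go-go family, 4 were expressed highly enough to be tested and 0 passed the threshold. KCNH4 (ENSDARG00000062565) stood at 12 ± 2.06 CPM (SD, n = 2) in longfin and 14.6 ± 3.02 CPM in wildtype tips, and KCNH1 (ENSDARG00000024167) at 3.47 ± 1.28 and 3.11 ± 0.0351 CPM. The log2 fold changes were -0.27 for KCNH4, 0.14 for KCNH1, 0.01 for *kcnh6a* and -0.69 for *kcnh7*. These 4 genes were too few for a set test. At an unadjusted p under 0.05, 0 of the 4 passed in edgeR, and DESeq2 called 0.

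Genes beside *kcnh2a* were examined because heterozygotes and clutchmates also differ by descent around the locus. The RefSeq annotation of the GRCz12tu assembly, which differs from the authors' GRCz11 build, was used only for gene order. In it 86 genes lie within 1 Mb of *kcnh2a*, 60 of them protein-coding. Of the 86 genes, 29 were matched to a counted gene and 22 were tested. None of the 22 passed edgeR's quasi-likelihood test with adjustment over all genes, where the lowest adjusted p was 0.0587, and 4 had an unadjusted p under 0.05. DESeq2 called 2 of them over all genes, *csrnp1a* and *pde4ca*. EdgeR called 1 neighbour over all genes with upper quartile scaling, with library size only and with no low count filter. Adjusted over the list alone, 3 passed, which are named here after their values were seen. The transcription factor gene *csrnp1a* had 5.76 ± 1.02 CPM in longfin and 22.9 ± 7.5 CPM in wildtype tips, a log2 fold change of -1.98 ± 0.27 (SE) with an adjusted p over the list alone of 0.00641. *csrnp1a* is also in the list of 85 early response genes described below, of which 8 rose and 11 fell. Whether its fall relates to its position was not tested. The phosphodiesterase gene *pde4ca* had a log2 fold change of -0.65 and an adjusted p over the list alone of 0.00991. The mitochondrial ribosomal protein gene *mrpl34* had 0.52 and 0.0386. The 4 nearest tested genes did not pass, with log2 fold changes of 0.32 for *map4l*, 0.16 for the K+-Cl- cotransporter gene *slc12a7a*, -0.87 for MYH7 (ENSDARG00000079782) and 0.13 for *trnau1apb*. The list-alone count was 0 without longfin heterozygous replicate 2, 1 without wildtype replicate 1 and 2 without longfin heterozygous replicate 1. A window of 2 Mb gave 5, adding *zgc:161973* and *thap4*.

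Of 18366 genes tested, 74 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 20 higher and 54 lower in longfin heterozygotes. The largest rise was in *egr1* (ENSDARG00000037421), an immediate early zinc finger transcription factor gene, from 66.4 ± 17.5 CPM in wildtype to 338 ± 34.8 CPM in longfin tips. KLF4 (ENSDARG00000079922), a transcription factor gene of epidermal barrier differentiation, fell from 212 ± 6.33 to 32.9 ± 6.68 CPM, a log2 fold change of -2.69 ± 0.14 (SE) with an adjusted p of 0.00372. The log2 fold changes of the 74 genes ranged from 0.61 to 3.28 in size. The CPM values of the 2 genotypes did not overlap in 7302 of the tested genes (39.8%), against 33.3% by chance in a comparison of 2 against 2. At an unadjusted p under 0.05 the counts were 1741 genes in all, 672 higher and 1069 lower. The count depended on single libraries, with 3 genes past the threshold without longfin heterozygous replicate 1 (KLF4, PELI1 and *si:dkey-165o8.2*, all lower), 1 without longfin heterozygous replicate 2 (KLF4) and 163 without wildtype replicate 2. It was 130 without the low count filter, 219 without composition scaling of the libraries, 289 with DESeq2, and 16 against a minimum fold change of 1.5. With the replicate number as a block the count was higher than any of these, as given below with the dependence on processing.

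Among the 12 largest rises were several transcription factor genes. Next to *egr1*, with a log2 fold change of 2.35 ± 0.19 and an adjusted p of 0.0204, stood PAX6 (ENSDARG00000103379), known from eye and neural development, at 2.13 ± 0.30 and 0.0485. PAX6 was low in both genotypes, with 5.17 ± 0.906 CPM in longfin and 1.2 ± 0.285 CPM in wildtype tips. The epithelial ETS factor gene ELF3 (ENSDARG00000077982) rose from 15.6 ± 4.15 to 47.6 ± 5.38 CPM. Both zebrafish copies of the immediate early response gene *ier2* rose, *ier2a* (ENSDARG00000099195) from 39.8 ± 5.30 to 130 ± 14.5 CPM and *ier2b* (ENSDARG00000086881) from 41.4 ± 6.76 to 139 ± 33.8 CPM. Of the AP-1 family, the subunit gene JUNB (ENSDARG00000074378) rose from 272 ± 25 to 655 ± 8.08 CPM and JDP2 (ENSDARG00000020133), which encodes a Jun-dimerizing repressor, from 123 ± 1.46 to 268 ± 10.6 CPM. The remaining rises were in *plekhs1.3* (log2 fold change 1.97), *arid6* (1.12), the stress-response gene GADD45B (ENSDARG00000013576, 1.12), the chemokine receptor gene CXCR4 (ENSDARG00000057633, 1.1) and the bZIP factor gene MAF (ENSDARG00000015890, 1.04).

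The 12 largest falls included further regulators. The deubiquitinase gene *usp2b* (ENSDARG00000074120) fell from 10.3 ± 1.88 to 1.05 ± 0.105 CPM, a log2 fold change of -3.28 ± 0.26 with an adjusted p of 0.00673. PELI1 (ENSDARG00000091592), which encodes a ubiquitin ligase of Toll and interleukin-1 receptor signalling, fell from 40.5 ± 2.39 to 7.17 ± 1.13 CPM. A second gene with that symbol, ENSDARG00000044083, had a log2 fold change of -0.16 and did not pass. The orphan nuclear receptor gene NR4A3 (ENSDARG00000055854) fell from 25.4 ± 0.483 to 5.80 ± 0.711 CPM, and NAB1 (ENSDARG00000040700), whose product is a corepressor of EGR proteins, from 12.6 ± 1.89 to 3.49 ± 0.724 CPM. The cAMP-responsive modulator gene *cremb* (ENSDARG00000102899) had a log2 fold change of -1.86 and the Src-like adaptor gene *sla2b* (ENSDARG00000020788) one of -2.24. Lower by a log2 fold change of -1.81 to -1.72 were PMP22 (ENSDARG00000060457), the Ral exchange factor gene RALGDS (ENSDARG00000042409), the lysophospholipid transporter gene MFSD2A (ENSDARG00000035909), the membrane protease gene *tmprss13b* (ENSDARG00000077573) and the metalloproteinase gene ADAMTS8 (ENSDARG00000007709). PAX6, *ier2b* and *sla2b* did not pass with limma voom or with a mean count of at least 50, and *ier2b* did not pass without the low count filter. Of 28 genes past the threshold, the 24 of both groups with *pkp3a*, ANXA1, *jag1a* and SLC2A1, 2 passed without longfin heterozygous replicate 1, 1 without longfin heterozygous replicate 2, 19 without wildtype replicate 1 and 24 without wildtype replicate 2, and KLF4 passed in each of these.

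**Figure D2:**
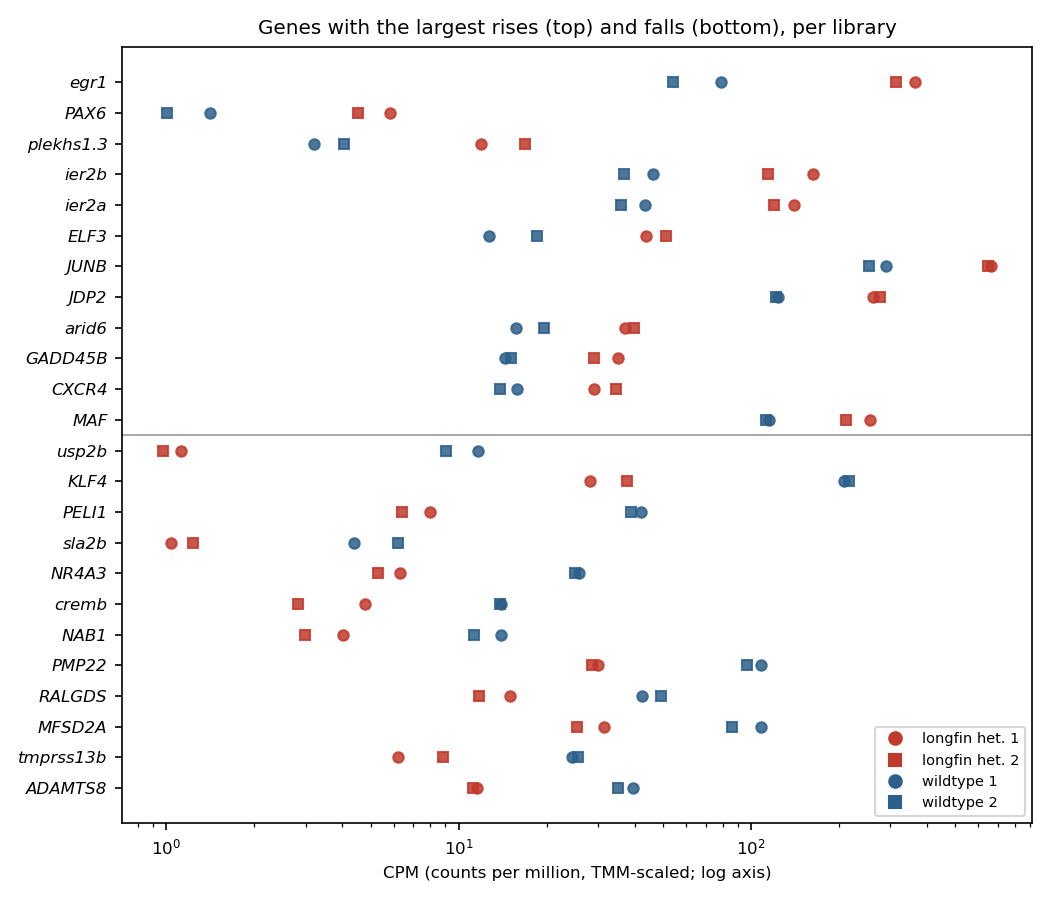
CPM of the 12 genes with the largest rises and the 12 with the largest falls among those of the 74 changed genes that met the naming rule, on a log axis. Each point is 1 library, longfin heterozygous in red and wildtype in blue, with circles for replicate 1 and squares for replicate 2. In each gene both longfin values lie on one side of both wildtype values, which the naming rule required, as in KLF4 with 28.1 and 37.6 against 208 and 217 CPM.

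Immediate early genes were the fixed group with the most changed members. Of 39 tested immediate early and heat shock genes, 6 rose and 0 fell with adjustment over all genes. These were *egr1*, *ier2a*, *ier2b*, JUNB, GADD45B and the stress-induced factor gene ATF3, the last with a log2 fold change of 0.71. None of the 6 is a heat shock gene. Adjusted over the list alone, 18 passed as higher and 5 as lower, and the lower ones, picked here after their values were seen, included *klf2a* at -1.06 and JUND at -0.68. The camera test placed the list above other genes with an adjusted p of 5.13e-20. With an estimated correlation between genes the adjusted p was 0.484.

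Superficial epidermal genes moved the other way. Of 36 tested genes of the superficial and intermediate epidermis, 3 fell and 0 rose with adjustment over all genes, and 14 passed as lower adjusted over the list alone. Besides KLF4, *pkp3a* (ENSDARG00000051861), which encodes a plakophilin of desmosomes, fell from 801 ± 63.0 to 385 ± 16.7 CPM, and ANXA1 (ENSDARG00000026726), an annexin gene, from 878 ± 12.7 to 575 ± 18.9 CPM. The list median was -0.25 on the log2 scale, with 28 of 36 genes below 0. The camera test gave an adjusted p of 6.93e-14 and, with an estimated correlation, an adjusted p of 0.484. The most abundant keratin genes of the list did not pass over all genes, among them *krt91* with a log2 fold change of -0.35 and *krt4* with -0.22. Basal and distal wound epidermis had 0 of 32 genes past edgeR's threshold, 8 at an unadjusted p under 0.05 with 4 in each direction, 2 higher and 1 lower adjusted over the list alone, and camera adjusted p = 0.276, with log2 fold changes of -0.14 for *krt5* and 0.08 for FREM2 (ENSDARG00000102626). Ionocyte and mucous cell genes were lower as a list of 12, with camera adjusted p = 0.0137 and adjusted p = 0.484 with an estimated correlation. None of the 12 passed on its own in edgeR over all genes, 3 were lower at an unadjusted p under 0.05, and 1 passed as lower adjusted over the list alone, the mucin gene *muc5.2* at -2.93 (adjusted p = 0.0124), which is named after its value was seen. ATP1B1 (ENSDARG00000013144) stood at -0.15 and *ca2* at -0.57. That list was not called without longfin heterozygous replicate 1 (adjusted p = 0.0919) or wildtype replicate 2 (0.0842), or with a mean count of at least 50 (0.103).

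Lists of outgrowth signalling, the blastema and fin matrix were placed above other genes by camera, each by a small shift and with 0 genes past edgeR's threshold over all genes. The Fgf list of 27 genes had a median log2 fold change of 0.17 and camera adjusted p = 5.79e-05, and 6 genes were higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 4 passed as higher, named here after their values were seen. These were the feedback inhibitor genes SPRY1, SPRY2 and SPRY4 with log2 fold changes of 0.68, 0.62 and 0.59, and FGF20 (ENSDARG00000086070) with 0.64. That FGF20 gene had 7.92 ± 0.00298 CPM in longfin and 5.07 ± 0.144 CPM in wildtype tips. A second gene with the symbol, ENSDARG00000007356, had 29.6 ± 5.37 and 31.0 ± 6.19 CPM, a log2 fold change of -0.06, and did not pass. The most abundant members of the Fgf list, DUSP6 and ETV4, were at 0.04 and 0.16. Its largest change was in DUSP1, at 1.39, which did not pass over the list alone (edgeR adjusted p = 0.0562) and is named after its value was seen. DUSP1 is also in the immediate early and heat shock list, so these lists are not independent. The blastema mesenchyme list of 48 genes had a median of 0.15 and camera adjusted p = 0.00139, with 13 genes higher and 3 lower at an unadjusted p under 0.05 and 5 higher and 1 lower adjusted over the list alone. Its most abundant members, POSTN (ENSDARG00000104267) and FN1 (ENSDARG00000006526), were at -0.01 and -0.03. The Hedgehog and Bmp list of 26 genes (median 0.08) had camera adjusted p = 0.0137, with BAMBI (ENSDARG00000055381) at 0.83 and GLI2 (ENSDARG00000025641) at 0.13. The Wnt list of 31 genes (median 0.08) had 0.0212, with DKK3 at 0.05 and WLS at 0.08. The actinotrichia and fibrillar matrix list of 37 genes (median 0.10) had 0.0497, with *col1a1a* at 0.28 and *and1*, a gene of the fin fold's actinodin fibres, at 0.34. With an estimated correlation the adjusted p was 0.484 for the Wnt, blastema and matrix lists and 0.497 for the Fgf and the Hedgehog and Bmp lists. Leaving out 1 library took the adjusted p to as much as 0.258 for Hedgehog and Bmp (wildtype replicate 2), 0.0872 for Wnt (longfin heterozygous replicate 2; 0.0775 without wildtype replicate 1) and 0.151 for the matrix list, which stayed past the threshold only without longfin heterozygous replicate 1 (0.0384). DESeq2's scaling took the matrix list to 0.0502 and a mean count of at least 50 took it to 0.0598.

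Of 10 tested K+ channel, cotransporter and gap junction genes linked to fin size, 17 calcineurin and NFAT genes and 17 voltage-gated Ca2+ channel genes, 0 passed edgeR's test over all genes or adjusted over the list alone, and DESeq2 also called 0. At an unadjusted p under 0.05 the counts were 2, 0 and 3. Camera gave adjusted p-values of 0.929, 0.473 and 0.467, and fry's test for change in either direction gave the Ca2+ channel list an adjusted p of 0.0318. The gap junction gene GJA1 (ENSDARG00000041799) had 229 ± 52.7 CPM in longfin and 227 ± 55.9 CPM in wildtype tips, and SLC12A7 (ENSDARG00000062058) had a log2 fold change of 0.26. The calcineurin regulator gene *rcan1a* stood at -0.01 and PPP3R1 (ENSDARG00000069360) at -0.10. CACNA1B (ENSDARG00000021735) and CACNA1G (ENSDARG00000089913) stood at 0.06 and 0.14.

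Of 34 S phase and 39 G2/M genes, 0 passed edgeR's test at an unadjusted p under 0.05, and DESeq2 also called 0, with camera adjusted p-values of 0.929 and 0.886. Camera called the G2/M list as higher without longfin heterozygous replicate 1 (adjusted p = 0.0414) and as lower without longfin heterozygous replicate 2 (0.0133) or wildtype replicate 1 (0.0108). The log2 fold changes were -0.05 for PCNA, -0.15 for RRM1, -0.13 for *mki67* and -0.02 for TOP2A. Osteoblast genes, whose labelled cells the dissection was meant to leave out, had 0 of 26 past the threshold over all genes and camera adjusted p = 0.22. COL10A1 (ENSDARG00000054753) was nevertheless abundant in both genotypes, at 2037 ± 229 CPM in longfin and 2357 ± 475 CPM in wildtype tips. DLX3 (ENSDARG00000014626) had a log2 fold change of 0.50 and passed adjusted over the list alone. DLX3 is also in the basal and distal wound epidermis list, among the 2 genes that were higher there adjusted over the list alone. Of 7 fin ray joint genes 0 passed over all genes (camera adjusted p = 0.929), with DLX5 at 0.36 and *hoxa13a* at 0.17. TNMD (ENSDARG00000052615), at -0.67, passed adjusted over the list alone (adjusted p = 0.00205) and is named after its value was seen, and DESeq2 called 1 gene of the list as lower. Of 17 matrix metalloproteinase genes and inhibitors 0 passed (0.162), with MMP2 at 0.03 and MMP14 (ENSDARG00000008388) at -0.01.

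Single members passed in 4 further lists that camera did not call. The Notch ligand gene *jag1a* (ENSDARG00000030289) fell from 116 ± 3.97 to 55.2 ± 1.44 CPM, as the 1 changed gene of 27 in the Notch and activin list (camera adjusted p = 0.886). The glucose transporter gene SLC2A1 (ENSDARG00000007412) fell from 87.6 ± 1.5 to 48.3 ± 0.80 CPM, as the 1 changed gene of 34 in the hypoxia and glycolysis list (0.162). For that list fry, which asks whether the genes move one way on balance, gave an adjusted p of 0.0378 as lower, the single call it made among 28 lists. The list's genes were nevertheless split, with 16 above 0, 18 below and a median log2 fold change of -0.0038. Camera with an estimated correlation gave an adjusted p of 0.497. CXCR4, listed with lymphocyte genes, was the 1 changed gene of 16 (0.295) and is also expressed outside lymphocytes. PMP22, listed with nerve and glia, fell from 103 ± 8.05 to 29.3 ± 1.05 CPM as the 1 changed gene of 18 (0.326) and is also a junction protein gene of epithelia.

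The other lists had 0 genes past edgeR's threshold over all genes. Across all 24 lists with a count of 0, limma voom also called 0 genes, the older edgeR fit called 1 (the pigment cell gene EDNRB) and DESeq2 called at least 1 gene in 10 lists. Camera adjusted p-values were 0.467 for 20 retinoic acid genes, 0.228 for 27 endothelial genes, 0.416 for 15 red blood cell genes and 0.557 for 26 macrophage and neutrophil genes. They were 0.228 for 19 pigment cell genes, 0.0822 for 22 interferon response genes and 0.22 for 13 mitochondrially encoded protein genes. Fry's test for change in either direction gave the interferon list an adjusted p of 0.000653. Adjusted over the list alone, 1 macrophage and neutrophil gene passed as higher and 1 pigment cell gene as lower. Examples were the retinoic acid genes CRABP2 (ENSDARG00000073978, -0.14) and CYP26A1 (-0.48), the vessel genes APLN (0.19) and *plvapb* (-0.46), the blood genes *hbaa1* (-0.02) and *slc11a2* (0.18), and the macrophage genes *apoeb* (0.16) and *cd74a* (-0.42), each as log2 fold change. Pigment cell genes CRIP2 and PAICS stood at -0.17 and -0.01, the interferon response gene *b2m* at -0.27, and MT-CO1 and MT-CO3 at 0.03 and -0.08. Of 26 skeletal muscle genes fixed as foreign to the fin ray, 4 were tested, too few for a set test, and 0 passed, with MYOG at -0.33 and TNNT3 (ENSDARG00000068457) at 0.11. Median, mean and camera direction differed in sign for the Notch, fin ray joint, nerve and glia, voltage-gated Ca2+ channel and lymphocyte lists. With an estimated correlation, camera called 0 of the 28 lists, with a lowest adjusted p of 0.484, against 8 with the preset correlation.

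**Figure D3:**
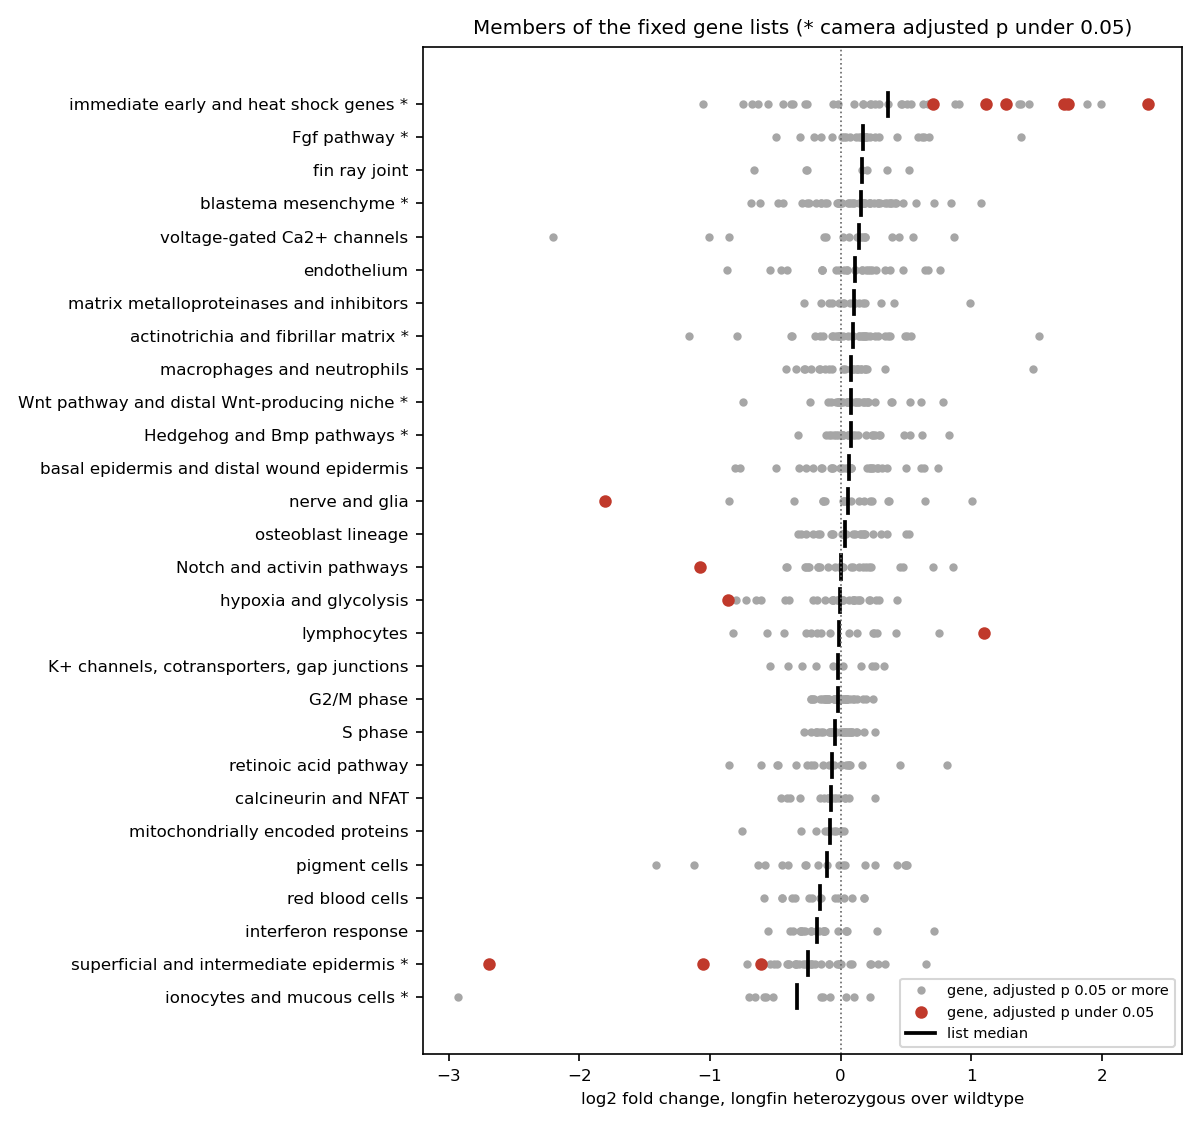
Log2 fold change of each tested gene in the 28 fixed lists that were tested as sets, longfin heterozygous over wildtype. Small grey points are genes that did not pass over all genes, red points are genes with an adjusted p under 0.05, black bars are list medians, and asterisks mark the 8 lists called by camera with the preset correlation. Medians lie between -0.33 for ionocytes and mucous cells and 0.37 for immediate early and heat shock genes.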

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

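The alternatives with no low count filter combined with the older fit or the block were chosen after the main results were seen. Against 74 changed genes, edgeR gave 130 with no low count filter, 219 with library size only, 16 with a minimum fold change of 1.5, and 347 with no filter and the older fit, and DESeq2 gave 289. Leaving out a library gave 1 to 163 genes, lowest without longfin heterozygous replicate 2 and highest without wildtype replicate 2, where 15.3% were higher against 27% of the 74. All 74 genes were among the calls of DESeq2 and of library size only. Other settings gave 62 to 91. Fewer samples account for some loss in the leave-one-out fits. For the rest the cause was not tested.

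The labels number the replicates 1 and 2 in each genotype but do not say that a number marks a shared clutch or day. With the number as a block, 794 genes passed, 245 higher and 549 lower, including all 74. The block leaves fewer degrees of freedom to estimate the spread. In the simulated data, which held no replicate effect, 28 of 190 calls of the block fit (14.7%) were false, against 9.77% without the block. With the block and no low count filter 328 passed. Deviations of same-numbered libraries correlated at 0.233 across genes, a hint from the data and not from the design. The block left 8 lists called, the same 8, and gave 4 neighbouring genes over the list alone and 3 over all genes.

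Of the fixed lists, 0 were called with an estimated correlation (lowest adjusted p 0.484) and 1 by fry, against 8 with the preset correlation. Leaving out a library gave 6 to 11, and other settings 7 to 9. The immediate early, superficial epidermis, Fgf and blastema lists passed in each leave-one-out fit. Without longfin heterozygous replicate 1 the G2/M list, not called in all libraries, was called in the opposite direction with a mean log2 fold change of 0.107. Its mean ranged from -0.161 to 0.116 in leave-one-out fits, and it was called as lower without longfin heterozygous replicate 2 or wildtype replicate 1. These shifts follow from the list's lower values in replicate 1 of both genotypes, since leaving out 1 library unbalances the replicate numbers. The endothelium, interferon response, matrix metalloproteinase, mitochondrially encoded protein, red blood cell and retinoic acid lists were also called with a library left out, endothelium in 2 such fits and the others in 1. A mean count of at least 50 added the nerve and glia and the hypoxia and glycolysis lists as lower, and no filter with the block added the mitochondrial list as lower. Fry's test for change in either direction passed for 9 lists, which were voltage-gated Ca2+ channels, Notch and activin, blastema, superficial epidermis, lymphocytes, nerve and glia, immediate early and heat shock, hypoxia and glycolysis, and interferon response.

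KCNH2 (ENSDARG00000029881) kept its direction in each setting that gave a value, with log2 fold changes from 3.74 to 5.52 in leave-one-out fits and 4.53 to 4.90 elsewhere. With no filter its adjusted p was 0.229, 0.104 with the block and 0.0365 with the older fit. DESeq2 gave no adjusted p. Without wildtype replicate 2 the wildtype count was 0 and no ratio was taken. ENSDARG00000106473 ranged from -1.39 to 1.2 in leave-one-out fits. Neither gene has a value at a mean count of 50 or in voom, the older fit or the block with the filter. Neighbouring genes past the threshold over the list alone numbered 3, with 5 in a 2 Mb window, 2 in a 500 kb window and 0 to 3 in leave-one-out fits. The older fit does not enter the list tests, and GC and chromosome alternatives were not run. With 2 libraries per genotype, depth limits KCNH2 and other low genes more than the abundant ones.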

Other observations

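The lists of desmosome genes, NF-kB pathway genes, clock genes and early response genes and the tests on the clock correlation, scaling, handling and the share of superficial cells were chosen only after their results were seen. Desmosome genes, which hold epithelial cells together, included 3 of 15 tested that fell in longfin tips with adjustment over all genes and 0 that rose. The list was put together after these falls were seen, so no list test is given. They were *pkp2*, from 188 ± 8.50 to 77.1 ± 3.91 CPM, *pkp3a*, and the desmoglein gene *dsg2.1*, from 972 ± 87.0 to 610 ± 18 CPM. DSP (ENSDARG00000022309), encoding desmoplakin, stood at 860 ± 83.6 CPM in longfin and 1253 ± 40.6 CPM in wildtype tips and did not pass. The list median was -0.51 on the log2 scale. Several members are also in the fixed superficial epidermis list, so the lists are not independent.

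Genes of the NF-kB pathway, named for the inflammatory transcription factor, included 4 of 20 tested that fell and 0 that rose. These were PELI1 (ENSDARG00000091592), N4BP1, from 114 ± 6.58 to 52.7 ± 5.09 CPM, TNFAIP3, encoding the deubiquitinase A20, from 46.7 ± 2.83 to 26.6 ± 2.39 CPM, and *tnfrsfa*, from 41.9 ± 0.423 to 24.6 ± 0.550 CPM. The cytokine gene *il1b* stood at 15.4 ± 0.456 CPM in longfin and 5.46 ± 1.91 CPM in wildtype tips, with an adjusted p of 0.067, and did not pass. The list median was -0.03, with 13 of 20 genes below 0.

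Clock genes differed between replicate 1 and replicate 2 in both genotypes. PER1 (ENSDARG00000056885) had 32.6 and 4.01 CPM in longfin heterozygous replicates 1 and 2 and 36.6 and 4.72 CPM in wildtype replicates 1 and 2, and NR1D1 had 26.6, 4.73, 27.8 and 5.64 CPM. A scaling difference between libraries is argued against, since a scaling factor moves all genes alike. Clock genes differed in both directions in longfin and wildtype, from 2.99 and 2.93 in PER1 (ENSDARG00000056885) to -0.87 and -1.07 in *cry3b*, as log2 of replicate 1 minus 2. Over all genes the median of this difference was -0.000269 in longfin and 0.0065 in wildtype. TMM scaling sets that median near 0, so it is no evidence on scaling. The median size of the clock genes' differences was 0.502 and 0.598. Their interquartile range was 0.938 in longfin and 1.05 in wildtype, above the upper 95% bounds of 0.388 and 0.408 in 10000 random lists matched on expression. The clock list was picked for such differences, so that last comparison was fixed in advance and tests no cause. Across 35 clock genes the replicate differences of the genotypes correlated at 0.845, which restates the pattern and tests no cause of it. Collection of the replicates at different times of day cannot be told apart from other differences between the replicate numbers, since no label gives a collection time. The fixed G2/M list was lower in replicate 1, with medians of -0.267 in longfin and -0.281 in wildtype. Division timed by the clock cannot be told apart from other differences between the libraries, because the list's genes vary together (camera's estimated correlation 0.864) and each difference is 1 library against 1.

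Early response genes moved in both directions between the genotypes. In a list of 85 such genes put together after the calls were seen, 8 rose, among them *egr1*, *ier2a* and JUNB (ENSDARG00000074378), and 11 fell, among them KLF4 and NR4A3. In the immediate early and heat shock list fixed in advance 6 rose and 0 fell over all genes, as a stronger response to handling in the longfin libraries would give. Adjusted over the list alone, 18 rose and 5 fell. Stronger handling or a different delay between cutting and lysis cannot be told apart from the genotype, because each would differ between the same libraries. Whether a lower share of superficial epidermal cells gave the 11 falls cannot be decided, because these genes were picked as called falls. Their median was -1.67, with a 95% bootstrap interval over the picked genes of -2.12 to -1.31. The 8 most abundant genes of the fixed superficial list had a median of -0.305 and ranged from -0.544 to -0.196. Even the smallest of the 11 falls, -0.812, was larger than those of these 8. Members of the superficial list moved unequally, with KLF4, itself 1 of the 11, at -2.69, *pkp3a* at -1.05 and 8 of 36 genes above 0. A lower share as the whole or a part of the cause stays open. A time of day that differed between the genotypes cannot be told apart from these values, since the slope of genotype change on replicate difference across clock genes was -0.172 with a 95% bootstrap interval of -0.43 to -0.0183. That interval resampled the clock genes as if they were independent and does not cover the spread between libraries. Between the genotypes 1 of 35 clock genes, BHLHE40, passed edgeR's test over all genes as higher and 0 passed as lower. BHLHE40 is also in the list of 85 early response genes. By fold change alone, 22 clock genes were below 0 and 13 above. The falls included *nr1d2a* at -1.63 (edgeR adjusted p = 0.699) and *hlfa* at -1.19 (0.0506), named after their values were seen.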
